A study of Mus musculus with 16 samples.

How the data were processed

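Brain RNA was sequenced from 16 mice, 4 for each combination of genotype label (wild type or Lcn2-/-) and injection (saline or LPS). Per the labels' protocols, total RNA was isolated from sonicated tissue with a Direct-zol kit and DNase I treatment on the column, and libraries followed standard Illumina protocols. The submitters' processing notes give the genome build mm10. The aligner, the counting tool, the annotation release and any filter are not given in the sources used here. The deposited table holds log2 RPKM after conditional quantile normalization by the authors, with 1 column per sample. The column names end in GeneCount, but the values are not whole numbers, include negative values, and have nearly the same 75th percentile and maximum in every library. No counts were analysed here, so the depth of each library and the counting error behind each value are unknown. There were 0 columns of per-sample values left unused.

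The lower part of the distribution differed between libraries: the lowest value lay between -8.56 and -7.01 in saline libraries and between -11.4 and -9.55 in LPS libraries. The 25th percentile lay between -4.12 and -2.73 in saline libraries and between -5.78 and -4.58 in LPS libraries. Of 33289 Ensembl gene IDs, 32695 (98.2%) were matched to a symbol and a position in GENCODE vM21, 594 were not, and 17 shared a symbol with a more highly expressed ID. Groups were taken from the genotype and injection labels, and every sample was used. The design text of the series gives 3 to 4 replicates of each genotype and injection combination, while 4 samples of each were present and used. The title of saline replicate 4 labelled Lcn2-/- alone ends in a letter, the meaning of which is not given in the sources used here. Each label describes a separate sample, so p-values measure the spread between these samples. All libraries expressed Y-linked genes (Ddx3y at a log2 RPKM of 3.20 or more) and little Xist (-4.40 at most).

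The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. A gene was tested if its log2 RPKM was at least -1 (0.5 RPKM) in at least 3 samples, which left 17349 genes and removed 15940. A group-means model was fitted to the deposited log2 values with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along the trend of the mean. The contrasts were LPS against saline in each genotype, genotype after each injection, and the interaction. Tests were two-sided, Benjamini-Hochberg adjustment ran over all genes tested, and a gene was called at an adjusted p under 0.05. Unless estimates are named, counts of genes higher, lower, rising or falling are counts of called genes. The threshold on 2-fold changes was applied to the estimated log2 fold change.

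There were 24 pathway lists and 20 lists of cell type and brain region markers, and 43 were tested; a list needed 3 tested members, and 1 list had too few. Lcn2 was left out of every list that held it, the pan-reactive astrocyte and the neutrophil list. Each was tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, whose directional p asks whether a set moves one way and does not compare it with other genes. The named genes were Lcn2, Slc22a17, the 8 largest increases and decreases among called genes whose groups did not overlap and whose mean log2 RPKM was at least 0 in the higher group, skipping predicted or unnamed genes, and from each list the 3 called members with the largest change in each direction and the uncalled member with the highest mean. The LPS response score was the mean log2 RPKM over 518 genes whose LPS effect, averaged over the genotypes, was called and at least 1 on the log2 scale, without Lcn2. It was compared by two-sided exact permutation of the genotype labels, within each treatment for the interaction, which tests for any genotype effect. LPS effects of the genotypes were compared by Deming regression with a jackknife SE that left out each library in turn.

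The procedure was tested on simulated data: 17349 genes were simulated as normal values with each gene's mean and residual spread in these libraries, of which 67, 67 and 66 were changed by 0.5, 1 and 2 on the log2 scale. For LPS in wild type, 71.6%, 85.1% and 100% of the genes changed by 0.5, 1 and 2 were called. For LPS in libraries labelled Lcn2-/- the shares were 70.1%, 86.6% and 100%, for genotype after saline 58.2%, 89.6% and 98.5%, for genotype after LPS 70.1%, 88.1% and 98.5%, and for the interaction 49.3%, 83.6% and 95.5%. False calls made up 6.56%, 4.47%, 4.65%, 6.04% and 7.32% of the calls in the 5 comparisons, in that order. In a simulated list test for genotype after LPS, camera and fry both called the raised list, and of the other lists camera called 0 and fry 1. The simulation used each gene's mean and spread but no correlation between genes. It therefore cannot show how often camera at the preset correlation makes false calls for correlated genes. Each gene also had the same simulated spread in every library. The shares above thus do not cover unequal spread between groups or a single library that stands apart. In the real libraries the estimated correlation ran from -0.032 for blood-brain barrier genes to 0.68 for choroid plexus markers.

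Alternatives to these choices were other filters, pseudocounts of 0.5 and 1 RPKM, median centring, quantile normalization, limma without trend or with robust moderation, array weights, fits to the compared groups alone, stricter thresholds, other gene sets for the score, removal of genes within 10 Mb of Lcn2, and leaving out each library in turn. A covariate for the block of columns in the table and the removal of GC content and length trends were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.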

Results

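RNA was sequenced from the hemi-brains of PBS-perfused C57BL/6J mice aged 3 to 4 months, 8 h after an injection of lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that activates innate immune cells, or of saline. The mice were labelled wild type or Lcn2-/-. Lcn2 encodes lipocalin-2, a secreted protein that binds bacterial siderophores and rises in acute inflammation. Each of the 4 combinations of genotype and injection had 4 libraries, 16 in all, and the title of the series names the question: whether lipocalin-2 affects the brain in inflammation. The deposited values were log2 RPKM, and 17349 of 33289 genes passed the filter on low values. The table gives no read counts, so the depth behind each value is unknown and no counting interval can be given. At 0.5 RPKM or above, 16372 to 16497 genes were measured in every library but 1; saline replicate 4 labelled Lcn2-/- had 17112. In a principal component analysis, component 1 (62.9% of the variance) separated LPS from saline libraries, and component 2 (11.8%) set that same saline replicate apart, at 0.885 against -0.186 to 0.130 for all others.

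Lcn2, the targeted gene (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252 in GRCm38, minus strand), had a value in every library. After saline it lay at 0.0650, 0.0741, 0.204 and 0.137 RPKM in wild type libraries and at 0.132, 0.204, 0.351 and 0.247 RPKM in libraries labelled Lcn2-/-. In wild type saline replicates 1 and 2 the log2 values (-3.94 and -3.75) lay near the 25th percentile of all genes (-4.09 and -3.98). Without counts, whether the transcript was detected there is unknown. After LPS, Lcn2 lay at 71.5, 67.8, 66.7 and 82.7 RPKM in wild type and at 40.2, 34.1, 38.3 and 37.2 RPKM in libraries labelled Lcn2-/-. The transcript was therefore present after LPS in all 4 libraries with the knockout label, at 52.0% of the wild type geometric mean, so the group is called "labelled Lcn2-/-" throughout. Which exons the reads came from is unknown, because the table holds 1 value per gene; a value from exons outside a deletion would not test the label. The difference after LPS was -0.94 ± 0.31 on the log2 scale (± SE, n = 4 per group), and the LPS libraries of the 2 genotypes did not overlap, but limma's adjusted p was 0.0505, just above the threshold. It passed on log2(RPKM + 0.5), with adjusted p = 9.9e-06, and over all alternatives the adjusted p ran from 6.9e-07 to 0.11. The main fit shares its estimate of spread across all groups. On the log2 scale the SD of Lcn2 was 0.77 in wild type and 0.59 in libraries labelled Lcn2-/- after saline. After LPS it was 0.14 and 0.098, so the saline libraries widen the SE of this difference. Slc22a17, which encodes a cell-surface receptor proposed for lipocalin-2, lay at 175, 181, 174 and 174 RPKM in wild type saline, labelled Lcn2-/- saline, wild type LPS and labelled Lcn2-/- LPS, and passed in no comparison (adjusted p from 0.26 to 0.94).

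**Figure D1:**
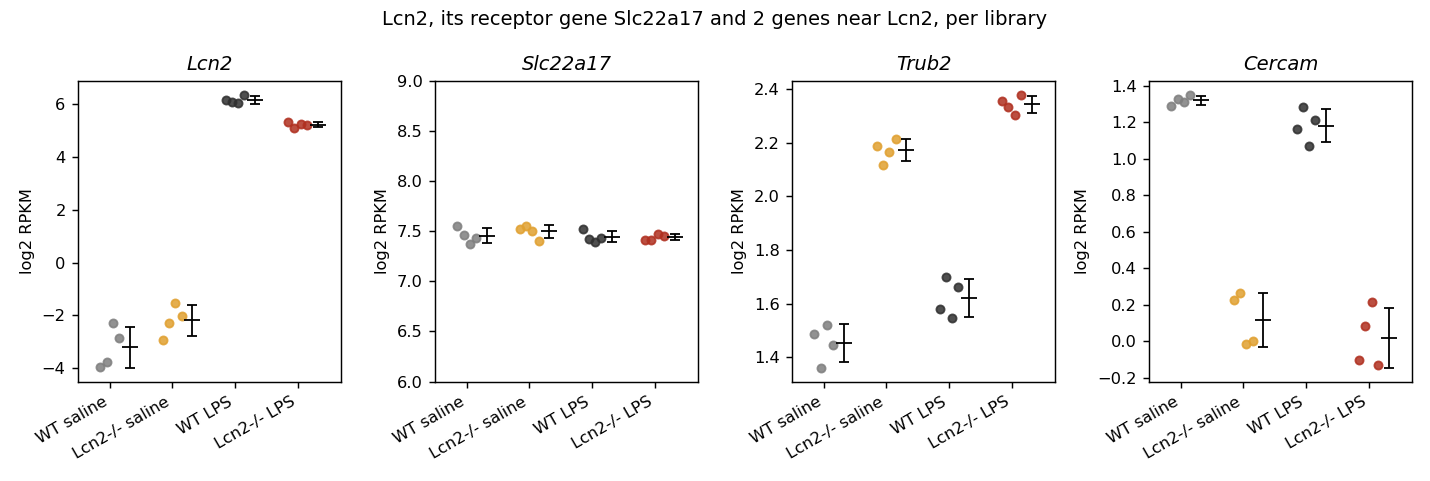
Log2 RPKM of Lcn2, Slc22a17, Trub2 and Cercam in each of the 16 libraries, with the mean and SD of each group of 4 beside its points; the vertical scale differs between panels. Lcn2 lay between 34.1 and 40.2 RPKM in the LPS libraries labelled Lcn2-/- and between 66.7 and 82.7 RPKM in wild type LPS libraries, while Trub2 and Cercam separated the genotype labels after either injection.

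The first comparison asked what LPS did to the wild type brain. Inflammatory genes led the increases. The acute phase gene Saa3 (serum amyloid A) rose 799-fold, Lcn2 itself 666-fold (log2 9.38 ± 0.31, ± SE, n = 4 against 4), and Csf3, the granulocyte colony-stimulating factor gene, 183-fold. Chemokine genes followed, with log2 fold changes of 6.26 ± 0.44 for Ccl5, 6.26 ± 0.33 for Cxcl1 and 5.78 ± 0.39 for Cxcl10. Serpina3f (6.43 ± 0.20), the transporter gene Slc10a6 (5.57 ± 0.34) and the matrix metalloproteinase gene Mmp3 (5.53 ± 0.44) completed the 8 largest increases besides Lcn2. The largest decreases were in Gkn3 (-5.64 ± 0.55), the amino acid transporter gene Slc38a5 (-3.36 ± 0.32), the microglial receptor gene Gpr34 (-3.34 ± 0.25), AU021092 (-2.97 ± 0.23), the activity-regulated transcription factor gene Egr2 (-2.62 ± 0.25), Slc40a1, which encodes the iron exporter ferroportin (-2.41 ± 0.22), Ushbp1 (-2.38 ± 0.14) and the angiopoietin receptor gene Tek (-2.36 ± 0.14). In all, 1980 genes rose and 2409 fell (limma, adjusted p under 0.05), of which 448 and 175 changed at least 2-fold.

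Most members of the innate immune lists rose in wild type brains. All 30 type I interferon response genes rose (median log2 2.04, camera adjusted p = 8.9e-35), among them Zbp1 (4.65 ± 0.25), Irf7 (4.12 ± 0.15) and Oasl1 (3.82 ± 0.27). Of 22 cytokine and chemokine genes, 20 rose (median 2.57, adjusted p = 1.4e-22); Il1a did not pass (0.80 ± 0.29, adjusted p = 0.053). The interferon gamma and GTPase list had 13 of 15 members higher, led by Gbp2 (4.19 ± 0.17), with Ido1 at -0.066 ± 0.17 and not passing. All 19 genes of MHC class I antigen presentation rose (median 0.88), including Tap1 (2.16 ± 0.16) and the class I transactivator gene Nlrc5 (3.00 ± 0.29). Of 20 NF-kB targets and feedback genes, 15 rose, such as Ch25h (4.97 ± 0.18), Bcl3 (3.62 ± 0.24) and Cd14 (3.13 ± 0.15), and Nfkbid fell (-0.41 ± 0.12). Complement and acute phase genes rose in 21 of 23 cases, with Saa2 at 5.15 ± 0.37 and Itih3 not passing (0.13 ± 0.11). Among myeloid activation genes 14 of 19 rose, led by Ms4a6d (4.13 ± 0.19) and Fcgr4 (4.06 ± 0.42). The inflammasome and lytic cell death list had 9 of 13 members higher, among them Casp4 (3.00 ± 0.20) and Mlkl (2.91 ± 0.27). Inhibitors of cytokine signalling moved both ways: 11 of 18 rose, including Socs3 (3.20 ± 0.11) and Il1rn (4.38 ± 0.29), and 5 fell, including the interleukin-10 receptor genes Il10ra (-0.61 ± 0.12) and Il10rb (-0.57 ± 0.067). Adjusted over the list alone, the counts were the same except for cytokines (21 higher) and myeloid activation (15 higher).

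Glial and vascular groups changed as well. Of 12 pan-reactive astrocyte genes, not counting Lcn2, 11 rose, led by Cxcl10, Steap4 (5.02 ± 0.22) and Timp1 (4.93 ± 0.17), while Vim did not pass (-0.10 ± 0.069). The A1 list had 10 of 12 and the A2 list 8 of 10 members higher, and the astrocyte marker gene Gfap rose by 1.39 ± 0.084. Homeostatic microglia genes fell in 13 of 18 cases (median -0.50), including Gpr34, P2ry12 (-2.07 ± 0.11) and Slc2a5 (-1.60 ± 0.17); the fatty acid receptor gene Gpr84, on the same list, rose (2.76 ± 0.24). Of the 10 microglia markers, 8 fell and 0 rose. Endothelial activation genes rose in 14 of 18 cases, such as P-selectin (Selp, 4.31 ± 0.29) and Lrg1 (3.43 ± 0.27), whereas Vwf (-1.02 ± 0.13), Icam2 (-0.77 ± 0.10) and Vegfa (-0.25 ± 0.071) fell. Blood-brain barrier genes divided, with 11 of 20 lower, among them the transporter genes Slco1a4 (-2.18 ± 0.16), Slco1c1 (-1.78 ± 0.069) and Abcb1a (-1.52 ± 0.11), and 4 higher, among them Mfsd2a (1.35 ± 0.085) and VE-cadherin (Cdh5, 1.21 ± 0.090). Of 12 endothelial cell markers, 6 fell and 3 rose. Myelin genes fell in 10 of 18 cases (12 adjusted over the list alone), with Opalin at -1.50 ± 0.094. Other counts adjusted over the list alone were the same, except that 2 myelin genes in place of 1 were higher.

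Glucocorticoid response genes rose in 20 of 23 cases (median 1.49, camera adjusted p = 1.8e-25), the same adjusted over the list alone, led by Plin4 (4.71 ± 0.14), Map3k6 (3.38 ± 0.11) and Cdkn1a (3.04 ± 0.073); Dusp1 fell (-0.43 ± 0.14). Immediate early genes fell in 16 of 23 cases and rose in 1 (17 and 1 adjusted over the list alone), with falls including Arc (-1.77 ± 0.16) and Nr4a3 (-1.39 ± 0.11). Oxidative stress genes rose in 13 of 23 cases and fell in 1 (13 and 2 adjusted over the list alone), with rises in Cybb (2.21 ± 0.22) and the metallothionein gene Mt2 (1.75 ± 0.073). Of 25 iron handling genes 7 rose, including ceruloplasmin (Cp, 2.53 ± 0.10), 6 fell and 12 did not pass (9 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.083). Synapse genes were not called (1 higher and 4 lower of 25, 1 and 3 adjusted over the list alone, adjusted p = 0.63), nor were oxidative phosphorylation (1 of 24 lower, 0 adjusted over the list alone, adjusted p = 0.063) or cytosolic ribosomal protein genes (0 of 25 passing in limma, median -0.028, adjusted p = 0.63).

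Camera called 19 of 24 pathway lists in this comparison, and 17 held with an estimated correlation; the exceptions were immediate early genes (adjusted p = 0.057 with an estimated correlation) and myelin (adjusted p = 0.084 with an estimated correlation). Lcn2 and Csf3 lay at 0.108 and 0.0468 RPKM after saline, a range in which libraries also differed in the low end of their distributions, so these folds depend on the scale: on log2(RPKM + 0.5), the changes were 6.87 for Lcn2 and 4.05 for Csf3. They were also nearer 0 for Gkn3 (-3.08), Serpina3f (3.07), Mmp3 (2.07), Slc10a6 (2.08), Zbp1 (1.89), Oasl1 (1.42), Nlrc5 (1.27), Mlkl (1.14), Il1rn (1.48), Selp (1.19), Slc2a5 (-0.70) and Cybb (0.78). When GC content and transcript length trends were removed from each library, 2455 genes were higher and 1987 lower, against 1980 and 2409 before, so the balance of the 2 directions changed.

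The second comparison asked the same of libraries labelled Lcn2-/-. The same kinds of genes led it. Saa3 rose 601-fold, Cxcl10 496-fold and Csf3 414-fold, and the chemokine genes Cxcl2 (7.65 ± 0.34), Cxcl1 (7.45 ± 0.33), Ccl5 (6.93 ± 0.44) and Ccl2 (6.83 ± 0.21) were, with Serpina3f (6.98 ± 0.20), the remainder of the 8 largest increases (log2, ± SE, n = 4 against 4). Lcn2 rose 170.0-fold (7.41 ± 0.31) in libraries with the knockout label. Gkn3 (-6.30 ± 0.55), the blood-brain barrier organic anion transporter gene Slco1a4 (-4.45 ± 0.16), Gpr34 (-4.07 ± 0.25) and AU021092 (-3.72 ± 0.23) fell most, followed by Slc38a5 (-3.61 ± 0.32), Inmt (-3.43 ± 0.33), Slc40a1 (-3.32 ± 0.22) and Egr2 (-3.21 ± 0.25). On log2(RPKM + 0.5) the changes were 5.59 for Csf3, 4.40 for Cxcl2, -3.09 for Gkn3, -1.66 for AU021092, -1.41 for Inmt and -1.42 for Slc40a1. Altogether 3588 genes rose and 4798 fell, 596 and 446 of them at least 2-fold; with GC content and length trends removed, 4466 were higher and 4084 lower.

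All 30 type I interferon genes (median 3.00), all 22 cytokine and chemokine genes (median 4.19), all 15 interferon gamma genes (median 2.94) and all 19 MHC class I genes (median 1.29) rose in libraries labelled Lcn2-/-. Rsad2 (6.30 ± 0.27), Mx1 (5.76 ± 0.36), Cd274, which encodes PD-L1 (3.94 ± 0.17), and Tap1 (3.42 ± 0.16) were among them. Of 20 NF-kB genes 19 rose, with Icam1 at 4.23 ± 0.10 and Nfkbid not passing (-0.25 ± 0.12). Complement and acute phase (21 of 23), myeloid activation (17 of 19), inflammasome (10 of 13), pan-reactive (12 of 12), A1 (10 of 12) and A2 astrocyte (10 of 10) and endothelial activation genes (14 of 18) rose in most cases. Cd68 fell (-0.31 ± 0.086), as did Vwf (-1.71 ± 0.13) and Icam2 (-1.36 ± 0.10). Inhibitors of cytokine signalling rose in 12 of 18 cases and fell in 2, with higher members such as Socs3 (4.22 ± 0.11) and Zfp36 (3.06 ± 0.12). Oxidative stress genes rose in 16 of 23 and fell in 2, with heme oxygenase 1 (Hmox1) at 2.15 ± 0.10.  Glucocorticoid response genes rose in 19 of 23 cases (median 0.88), and the clock gene Per2 fell (-1.28 ± 0.13). Each of these lists was called by camera, and all counts were the same when adjusted over the list alone.

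Homeostatic microglia genes fell in 15 of 18 cases, with P2ry12 at -2.16 ± 0.11, and microglia markers in 9 of 10; Gpr84 (3.71 ± 0.24) and Fcrls (0.28 ± 0.073) rose. Blood-brain barrier genes fell in 11 of 20 cases and rose in 5, among them Cdh5 (1.99 ± 0.090) and Esam (0.90 ± 0.052). Of 12 endothelial cell markers, 7 fell and 2 rose (8 and 2 adjusted over the list alone). Their camera adjusted p was 0.025, and 0.15 with an estimated correlation. Myelin genes fell in 11 of 18 cases and rose in 2. Immediate early genes fell in 13 of 23 and rose in 4 (15 and 4 adjusted over the list alone), with Arc at -2.92 ± 0.16 and Npas4 at -2.47 ± 0.27; Jun (0.58 ± 0.055) and Gadd45b (0.70 ± 0.080) rose. Cytosolic ribosomal protein genes rose in 14 of 25 cases (16 adjusted over the list alone, median 0.15). Iron handling genes rose in 8 and fell in 5 of 25 cases. Synapse genes fell in 9 of 25 cases and rose in 4 (10 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.19); Shank1 (-0.57 ± 0.080) and Homer1 (-0.62 ± 0.073) were among the genes that fell. Grin1 (0.32 ± 0.10) and Nlgn1 (0.26 ± 0.058) rose. Oxidative phosphorylation was not called (6 higher, 3 lower, adjusted p = 0.29; 2 and 1 adjusted over the list alone).

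Camera called 21 of 24 pathway lists here and 15 held with an estimated correlation. The call was lost for homeostatic microglia (adjusted p = 0.054 with an estimated correlation), blood-brain barrier (0.062), ribosomal proteins (0.15), immediate early genes (0.22), iron handling (0.24) and myelin (0.39).

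**Figure D2:**
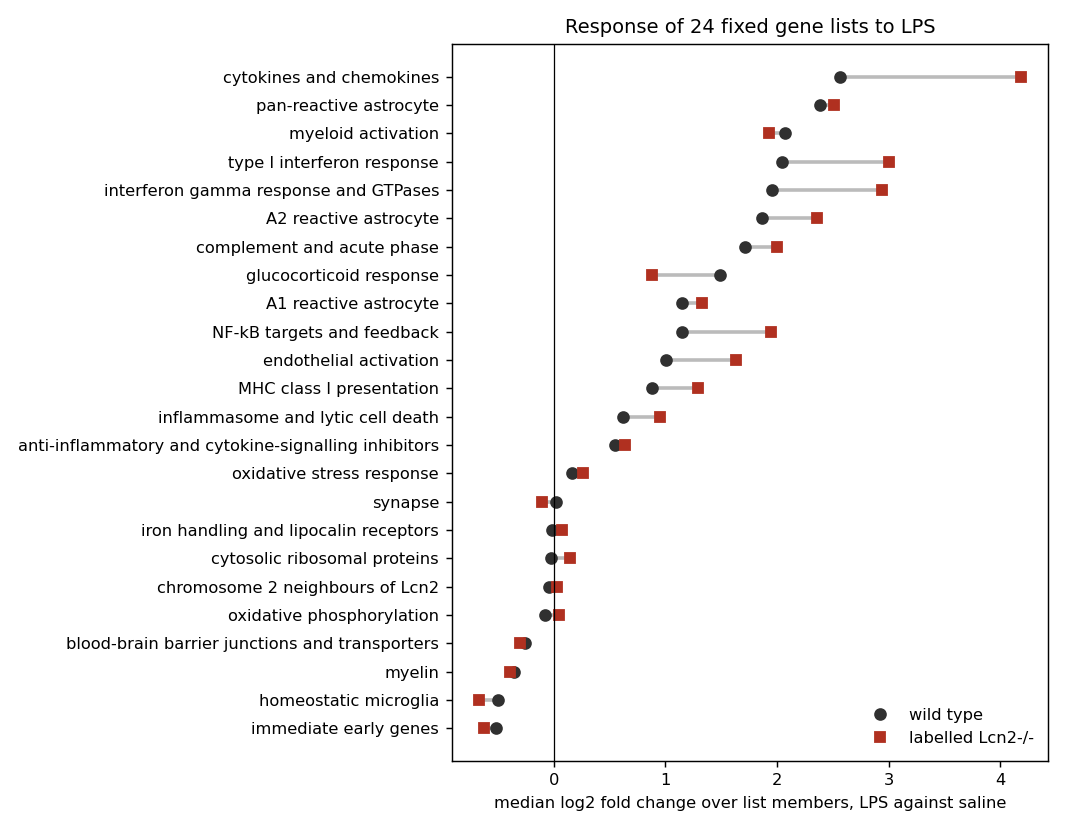
Median log2 fold change over the members of each of 24 gene lists, LPS against saline, in wild type libraries (circles) and in libraries labelled Lcn2-/- (squares), each from 4 against 4 libraries; lines join the 2 genotypes. Cytokine and chemokine genes lay at 2.57 in wild type and 4.19 in libraries labelled Lcn2-/-, and glucocorticoid response genes at 1.49 and 0.88.

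The third comparison asked whether the genotype label alone changed the brain, after saline. Few genes differed. Trub2, a tRNA pseudouridine synthase homologue, was higher in libraries labelled Lcn2-/- (log2 0.72 ± 0.048, ± SE, n = 4 against 4; 2.74 against 4.51 RPKM), and Cercam was lower (-1.20 ± 0.089; 2.50 against 1.09 RPKM). The other genes past the threshold were Tmem181b-ps (0.69 ± 0.031), Col5a1 (0.40 ± 0.062), Ntng2 (0.34 ± 0.051), Camkk1 (0.20 ± 0.031) and Gm26659 (1.08 ± 0.18), a non-coding RNA named although the rule for named genes skips it and chosen after its value was seen, all higher, and the axon guidance gene Slit2 (-0.51 ± 0.080), which was lower. On log2(RPKM + 0.5) Gm26659 did not pass (0.67, adjusted p = 0.081). Trub2, Cercam, Col5a1 and Ntng2 lie on chromosome 2 within 10 Mb of Lcn2, at 29761224 to 29788502, 29869164 to 29882840, 27886425 to 28039514 and 29194541 to 29253005 in GRCm38. Tmem181b-ps is a pseudogene copy, so its reads could not be told apart here from those of related copies. Lcn2 was at 1.03 ± 0.31 and did not pass (adjusted p = 0.37). Limma called 8 genes in all, against 1897 at an unadjusted p under 0.05.

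Glucocorticoid response genes lay higher in libraries labelled Lcn2-/- after saline in all 23 cases by estimate (median 0.22, camera adjusted p = 7.5e-11). None of these genes passed limma's test over all genes, 8 did when adjusted over the list alone, and adjusted p = 0.35 with an estimated correlation. Striatal markers were called higher (median 0.10, adjusted p = 0.027, and 0.65 with an estimated correlation). Immediate early genes (median 0.11, adjusted p = 0.0029) and synapse genes (median 0.045, adjusted p = 0.028) were also called higher by camera, and myelin genes lower (median -0.12, adjusted p = 4.0e-04), as were oligodendrocyte markers (median -0.11, adjusted p = 4.0e-04). With an estimated correlation none of these calls held (adjusted p from 0.35 to 0.70). The mean log2 RPKM of synapse genes was 5.24 in saline replicate 4 labelled Lcn2-/-, against 5.16 in the others of its group. Over the list alone, 6 immediate early genes and 1 synapse gene and 1 striatal marker were higher, 3 oligodendrocyte markers were lower and 0 myelin genes passed. Cytokine and chemokine genes had no member past limma's test over all genes (1 adjusted over the list alone; median 0.24, camera adjusted p = 0.24), nor had type I interferon genes (0 adjusted over the list alone; median 0.029, adjusted p = 0.90).

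Saline replicate 4 labelled Lcn2-/- stood apart from its group, and without it 13 genes and 9 pathway lists were called, against 8 and 4 with it. With GC content and length trends removed, 6 genes were higher and 1 was lower, against 6 and 2 before. The count lay at 3 without wild type saline replicate 2 or 3 or labelled Lcn2-/- saline replicate 1 or 3, at 4 without wild type saline replicate 1 or labelled Lcn2-/- LPS replicate 2, and at 5 without wild type saline or LPS replicate 4.

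The comparison of the genotype labels after LPS asked whether the inflamed brains differed. Inflammatory genes were higher in libraries labelled Lcn2-/-, a direction that rests on the labels. The Lcn2 transcript was lower in these libraries but not absent, so it does not settle whether they are knockouts. The interferon-induced chemokine genes Cxcl11 and Cxcl10 were 14.4-fold and 7.68-fold higher (log2 3.85 ± 0.42 and 2.94 ± 0.39, ± SE, n = 4 against 4), and the antiviral gene Rsad2 6.62-fold higher (2.73 ± 0.27). Cxcl11 lay at only 0.118 RPKM in wild type LPS libraries, and on log2(RPKM + 0.5) its difference was 1.82, below the 2.89 of Cxcl10. On the same scale Acod1 was at 1.41, Sema3g at -0.79 and Sox18 at -0.68, nearer 0 than the values that follow. Ptx3 (2.70 ± 0.42), Ccl7 (2.50 ± 0.29), Cxcl2 (2.47 ± 0.34), Calhm6 (2.46 ± 0.29) and Acod1, which makes itaconate in activated myeloid cells (2.46 ± 0.37), followed. Slco1a4 was 5.06-fold lower (4.71 against 0.931 RPKM). Srarp (-1.91 ± 0.25), the semaphorin gene Sema3g (-1.35 ± 0.13), Cercam (-1.16 ± 0.089), the Notch target gene Nrarp (-1.16 ± 0.092), the endothelial transcription factor gene Sox18 (-1.16 ± 0.18), Snora34 (-1.15 ± 0.21) and Npas4 (-1.05 ± 0.27) were also lower. In total 1222 genes were higher and 1517 lower, 139 and 54 of them at least 2-fold; with GC content and length trends removed, 1494 were higher and 1375 lower.

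Type I interferon genes were higher in 26 of 30 cases (28 adjusted over the list alone; median 0.93, camera adjusted p = 2.4e-26), with Mx2 at 2.29 ± 0.20 and Bst2 not passing (0.26 ± 0.13). Cytokine and chemokine genes were higher in 16 of 22 cases (21 adjusted over the list alone; median 1.50), and Ccl5 did not pass (0.98 ± 0.44). Interferon gamma genes were higher in 14 of 15 cases, including Cd274 (1.74 ± 0.17) and Irgm1 (1.43 ± 0.15), and MHC class I genes in 17 of 19, including H2-Q6 (1.45 ± 0.23) and Tap1 (1.43 ± 0.16), although H2-Q genes are close paralogs whose reads this table cannot tell apart. NF-kB targets and feedback genes were higher in 15 of 20 cases, among them Cd40 (1.90 ± 0.30, or 1.03 on log2(RPKM + 0.5)), Icam1 (1.41 ± 0.10) and Tlr2 (1.41 ± 0.21). Inhibitors of cytokine signalling were higher in 11 of 18 cases, such as Tnfaip3 (1.30 ± 0.13), Socs1 (1.26 ± 0.25) and Socs3 (1.10 ± 0.11), while Tsc22d3 was lower (-0.34 ± 0.079). Inflammasome (6 of 13), myeloid activation (7 of 19) and A2 astrocyte genes (8 of 10) were called higher too, with Mlkl at 1.34 ± 0.27, Cd14 at 1.31 ± 0.15 and Tgm1 at 1.53 ± 0.35 (0.86 on log2(RPKM + 0.5)). Camera called oxidative stress genes higher, with 3 of 23 higher and 1 lower: Hmox1 was at 0.90 ± 0.10, the cystine transporter gene Slc7a11 at 0.53 ± 0.070 and Gclm at -0.18 ± 0.060. Adjusted over the list alone, higher members numbered 15 for interferon gamma, 18 for MHC class I, 17 for NF-kB, 12 for cytokine-signalling inhibitors, 9 for inflammasome, 9 for myeloid activation, 10 for A2 and 4 for oxidative stress, and lower members 1 for cytokine-signalling inhibitors, 1 for myeloid activation and 2 for oxidative stress.

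Pan-reactive astrocyte genes (5 of 12 higher, 7 adjusted over the list alone), A1 genes (6 higher and 1 lower of 12, 6 and 2 adjusted over the list alone), endothelial activation genes (6 higher and 3 lower of 18, 9 and 4 adjusted over the list alone), complement and acute phase genes (4 higher and 2 lower of 23, the same adjusted over the list alone), oxidative phosphorylation (2 of 24 higher, the same adjusted over the list alone) and ribosomal protein genes (8 of 25 higher, 9 adjusted over the list alone) were called by camera with the preset correlation. The adjusted p of these lists was 0.056 to 0.42 with an estimated correlation. The iron exporter gene Slc40a1 was lower (-1.21 ± 0.22, or -0.31 on log2(RPKM + 0.5)) while Hmox1 was higher, and the iron handling list was not called (adjusted p = 0.40). Blood-brain barrier genes were lower in 7 of 20 cases, such as Lsr (-0.89 ± 0.13) and occludin (Ocln, -0.59 ± 0.11), and higher in 2, among them Cdh5 (0.81 ± 0.090), the same adjusted over the list alone, with the list not called (adjusted p = 0.11). Glucocorticoid response genes divided (4 higher, 7 lower, 12 not passing; 5 and 7 adjusted over the list alone; list adjusted p = 0.73): Cebpb (0.77 ± 0.19) and Nfkbia (0.49 ± 0.11) were higher, and Arrdc2 (-0.65 ± 0.14) and Pdk4 (-0.54 ± 0.091) were lower. Homeostatic microglia (5 lower and 2 higher of 18, 6 and 2 adjusted over the list alone, adjusted p = 0.15), immediate early (5 higher and 2 lower, 6 and 3 adjusted over the list alone, adjusted p = 0.094), synapse (1 higher and 3 lower, 2 and 4 adjusted over the list alone, adjusted p = 0.18) and myelin genes (adjusted p = 0.39) were not called. Neutrophil markers had 0 of 7 members past limma's test (0 adjusted over the list alone; camera adjusted p = 0.39), with S100a9 at 0.47 ± 0.30, and monocyte markers had Plac8 higher (1.03 ± 0.31) and Ly6c2 lower (-0.66 ± 0.20), at 0.58 and -0.42 on log2(RPKM + 0.5). Erythrocyte markers had 1 of 6 higher (2 adjusted over the list alone; median 0.63, camera adjusted p = 0.073).

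Camera called 16 of 24 pathway lists in this comparison and 10 held with an estimated correlation (adjusted p from 0.0053 to 0.041). The call was lost for ribosomal proteins (adjusted p = 0.056 with an estimated correlation), pan-reactive astrocyte (0.16), endothelial activation (0.18), oxidative phosphorylation (0.37), complement (0.40) and A1 genes (0.42). The count of 2739 genes became 5169 without saline replicate 4 labelled Lcn2-/-, which enters through the shared spread, and 1511, 1733, 1750 and 1782 without labelled Lcn2-/- LPS replicate 3, wild type LPS replicate 3, wild type LPS replicate 1 and labelled Lcn2-/- LPS replicate 2.

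The interaction of genotype label and treatment tested whether the LPS effect itself differed. The 8 largest positive interactions among named genes included chemokine and interferon-induced genes. The LPS effect was larger in libraries labelled Lcn2-/- by 3.90 ± 0.59 for Cxcl11, 3.18 ± 0.55 for Cxcl10, 2.70 ± 0.38 for Rsad2, 2.68 ± 0.41 for Calhm6, 2.68 ± 0.30 for Ccl2, 2.55 ± 0.48 for Cxcl2, 2.48 ± 0.28 for Mx2 and 2.43 ± 0.41 for Ccl7 (log2, ± SE, n = 4 per group). It was lower for Slco1a4 (-2.27 ± 0.23), which fell in both genotypes and further with the knockout label, and for Srarp (-1.91 ± 0.35), DQ267100 (-1.73 ± 0.39), Kpna2-ps (-1.64 ± 0.37), Sema3g (-1.50 ± 0.18), Lrg1 (-1.48 ± 0.39), the somatostatin receptor gene Sstr4 (-1.45 ± 0.36) and Sox18 (-1.37 ± 0.26). Lcn2 rose less in libraries labelled Lcn2-/- (-1.97 ± 0.44, limma adjusted p = 0.016). On log2(RPKM + 0.5) the interaction was 1.83 for Cxcl11, below 2.97 for Cxcl10 and 2.54 for Rsad2, and -1.17 for Lcn2, whose saline values lay between 0.0650 and 0.351 RPKM. Other values also shrank on that scale, to 1.77 for Calhm6, -0.98 for DQ267100, -0.66 for Kpna2-ps, -0.90 for Sema3g, -0.92 for Sstr4 and -0.86 for Sox18. The interaction was called positive for 677 genes and negative for 853. With GC content and length trends removed, the counts were 791 and 799.

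Of 30 type I interferon genes, limma called 20 with a positive interaction (23 adjusted over the list alone). The list median was 0.92 (camera adjusted p = 6.4e-19, and 0.061 with an estimated correlation). Also called positive were 13 of 20 NF-kB genes (14 adjusted over the list alone, median 0.74) and 11 of 22 cytokine and chemokine genes (14 adjusted over the list alone, median 1.19). The same held for 10 of 15 interferon gamma genes (14 adjusted over the list alone, median 1.10) and 9 of 19 MHC class I genes (14 adjusted over the list alone, median 0.53). With an estimated correlation the adjusted p was 0.061 for cytokines, 0.061 for interferon gamma and 0.14 for MHC class I. Irf1 (1.56 ± 0.17), Cd40 (1.87 ± 0.42, or 1.02 on log2(RPKM + 0.5)) and Tap1 (1.26 ± 0.23) were among the positive ones. Ch25h had a negative interaction (-0.88 ± 0.26), which did not pass on that scale (-0.47), and B2m did not pass (0.013 ± 0.059). Glucocorticoid response genes moved the other way, with 10 of 23 called negative (11 adjusted over the list alone), among them Per2 (-1.10 ± 0.18), Arrdc2 (-0.94 ± 0.20) and Fkbp5 (-0.44 ± 0.094). The list median was -0.44 (camera adjusted p = 0.0014, and 0.36 with an estimated correlation). Part of this lies in saline, where the list was higher in libraries labelled Lcn2-/- (median 0.22). After LPS the genotype difference of the list was not called (median -0.10, camera adjusted p = 0.73). Camera called 17 of 24 pathway lists, but only NF-kB targets and feedback held with an estimated correlation (adjusted p = 0.029). Camera also called marker lists: erythrocyte (median 1.09, 0 of 6 members past limma's test, 5 higher and 1 lower adjusted over the list alone), cerebellum (median 0.17, 3 higher, 5 adjusted over the list alone) and oligodendrocyte markers (median 0.14, 0 passing, 0 adjusted over the list alone) with positive interactions, and olfactory bulb markers (median -0.80, 2 lower, 3 adjusted over the list alone) with negative ones. Their adjusted p was 0.016 to 0.034, and 0.28 to 0.44 with an estimated correlation. The count of 1530 genes became 740, 764, 780, 857, 898, 1000 and 1010 without wild type LPS replicate 1, wild type saline replicate 3, labelled Lcn2-/- LPS replicate 3, labelled Lcn2-/- LPS replicate 2, wild type saline replicate 4, and wild type LPS replicates 2 and 3.

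A score per mouse, the mean log2 RPKM over 518 genes that rose at least 2-fold with LPS averaged over both genotypes, gave the size of the response in single values. It was -0.83 ± 0.051 (SD, n = 4) in wild type and -0.77 ± 0.024 in labelled Lcn2-/- saline libraries, and 1.10 ± 0.12 and 1.72 ± 0.058 after LPS. After LPS the score was higher by 0.62 in libraries labelled Lcn2-/-, with all 4 above the 4 wild type libraries (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give), and the LPS effect was larger by 0.57 (two-sided exact permutation p = 0.0265 over 4900 assignments). That permutation tests for any genotype effect, so its p does not separate an interaction from the genotype difference after LPS. After saline the difference was 0.054 (exact permutation p = 0.171). The genes of the score were chosen on these libraries, symmetrically in genotype.

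**Figure D3:**
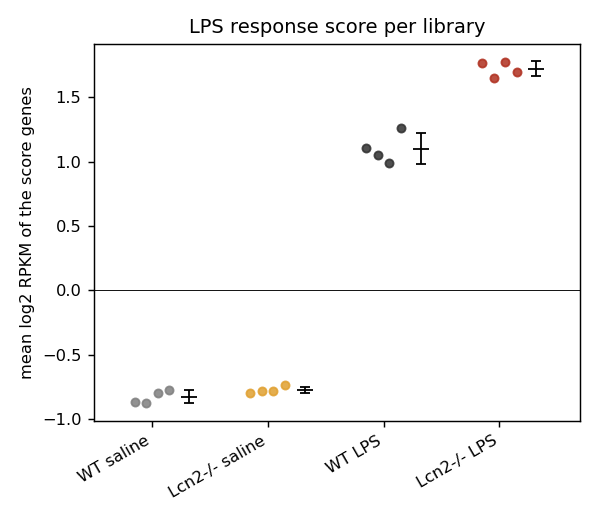
LPS response score, the mean log2 RPKM over 518 genes that rose with LPS, in each of the 16 libraries, with the mean and SD of each group of 4 beside its points. The LPS libraries labelled Lcn2-/- lay between 1.65 and 1.77, above the wild type LPS libraries, which lay between 0.99 and 1.26.

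Across the 17349 genes the LPS effects of the 2 genotypes, which share no library, correlated with a Pearson r of 0.83 and a Spearman rho of 0.588; genes are not independent replicates. Of the genes called, 1529 rose in both genotypes, where independent lists of these sizes would share 409, and 1771 fell in both, against 666 for independent lists. Only 32 genes were called in opposite directions. The Deming slope of the effects in libraries labelled Lcn2-/- on those in wild type was 1.40 (jackknife SE 0.108). Of 1530 interaction calls, 470 changed with LPS in both genotypes, 915 in libraries labelled Lcn2-/- alone, 127 in wild type alone and 18 in neither. A list's median, mean and camera direction differed in sign for 4, 3, 7, 1 and 5 of 43 lists in the 5 comparisons, in the order given here, and 0 of those lists were called by camera.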

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

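The tests on low values, on leukocyte genes, on swapped labels, on the remaining part of the locus and on strain sequence were chosen only after the result was seen, and the removal of GC and length trends was added after the data were seen; the carry-over test and the counts of splits were planned before their results.

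By the interaction test, camera called a larger LPS effect in libraries labelled Lcn2-/- for several inflammatory lists. Complement and acute phase (median 0.10, camera adjusted p = 0.27) and endothelial activation genes (median 0.084, camera adjusted p = 0.27) were not called. With an estimated correlation, NF-kB targets alone passed (adjusted p = 0.029). The adjusted p of the other called lists in this paragraph was then 0.061 to 0.44, with cytokine and interferon lists at the lower end. The median interaction (log2) was 1.19 for cytokines and chemokines, 0.74 for NF-kB targets and feedback, 0.92 for type I interferon, 1.10 for interferon gamma and 0.53 for MHC class I genes. It was 0.47 for pan-reactive, 0.31 for A1 and 0.80 for A2 astrocyte genes, 0.31 for myeloid activation, 0.42 for inflammasome genes and 0.37 for inhibitors of cytokine signalling. The interaction was negative for glucocorticoid response genes (-0.44) and synapse genes (-0.13), and positive for oxidative stress (0.061), myelin (0.14), oxidative phosphorylation (0.096) and ribosomal protein genes (0.17). Single genes with a larger LPS effect were Cxcl11 (3.90), Cxcl10 (3.18), Rsad2 (2.70), Calhm6 (2.68), Ccl2 (2.68), Cxcl2 (2.55), Mx2 (2.48) and Ccl7 (2.43). The LPS effect was lower in libraries labelled Lcn2-/- for Slco1a4 (-2.27), Srarp (-1.91), DQ267100 (-1.73), Kpna2-ps (-1.64), Sema3g (-1.50), Lrg1 (-1.48), Sstr4 (-1.45), Sox18 (-1.37) and Lcn2 (-1.97). On log2(RPKM + 0.5) values moved most in proportion for Cxcl11 (1.83), Calhm6 (1.77), Kpna2-ps (-0.66), DQ267100 (-0.98), Sema3g (-0.90), Sstr4 (-0.92), Sox18 (-0.86) and Lcn2 (-1.17). The count of genes was 1530 and the difference of the response score was 0.57.

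Members of the cytokine, NF-kB, interferon and MHC class I lists had a median interaction of 0.908. Low values normalized differently between libraries would leave members with a mean log2 RPKM of 2 or more near 0. The median of those 24 members was 0.49 and 100% of their estimates were positive. Removing GC content and length trends left the median of all 106 members at 0.907. If more blood neutrophils with unchanged output per cell were the whole cause, S100a8 and S100a9 would rise by about the cytokine median of 1.50. They differed by 0.363 ± 0.341 (SE), with an upper bound of 1.03, which argues against that case only. A higher output per neutrophil was not tested. Blood stays open: 9 tested monocyte and lymphocyte markers had a median difference of 0.037, with 1 called higher (Plac8, 1.03) and 2 called lower (among them Ly6c2, -0.66), and 6 erythrocyte markers a median of 0.63 (1 called higher, fry adjusted p = 0.040, camera 0.073), but these changed with LPS by a median of -0.76 in wild type and 0.31 in libraries labelled Lcn2-/-, so much of their difference lies in a fall in wild type. A response that depends on the genotype may remain as a hypothesis, but so may other differences between the labelled groups that these libraries do not test, and the Lcn2 transcript leaves the nature of the genotype itself open.

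The Lcn2 transcript reached 52.0% of the wild type level after LPS in libraries labelled Lcn2-/-. Swapped labels would put libraries on the wrong side for Cercam and Trub2, but 8 of 8 LPS libraries lay on the side of their label for both genes, which argues against a swap confined to the LPS groups; an exchange of the genotypes in both treatments would also give 8 of 8, would turn every genotype direction around and is not excluded, though it would put Lcn2 after LPS at 66.7 to 82.7 RPKM in knockouts, above 34.1 to 40.2 in wild type. Reads carried over from wild type LPS libraries in the amount that the Lcn2 level needs would allow a Cercam difference of -0.46, and the difference was -1.16 ± 0.089 (SE). Transcription through a part of the locus that the targeting left in place may give such a level (Lcn2 differed by -0.94), and it cannot be told apart from an intact transcript, because the table holds 1 value per gene.

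Of the 8 genes called between the genotypes after saline, 4 lay within 10 Mb of Lcn2, where 1.75% of tested genes lie (two-sided Fisher's exact p = 6.0e-06). After LPS, 3 of the 4 passed in the same direction, and Ntng2 had an adjusted p of 0.060; of the 4 genes outside the region 3 also passed in the same direction, so persistence is not particular to it. Strain sequence kept around Lcn2 from the targeted embryonic stem cells is a candidate explanation; no sequence was analysed here, and an effect of Lcn2 itself on its neighbours stays open and untested.

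Chance was weighed by other splits of the same libraries. For LPS in wild type, 1 of 35 splits, the real one, gave as many calls (4389, highest other 1). The same held in libraries labelled Lcn2-/- (1 of 35, 8386, highest other 6). It also held for genotype after LPS (1 of 35, 2739, highest other 0). A share of 1 in 35 is the smallest that these splits can give, so chance is made less likely but not excluded. Where the groups differ, other splits mix them, which widens the spread within groups and lowers their counts. For genotype after saline, 2 of 35 splits gave as many calls as the real 8 (highest other 8), so chance cannot be excluded for the count. For the interaction, 2 of 100 drawn regroupings gave as many calls as the real 1530 (highest other 1724), but these draws do not exclude chance for the interaction. The 94 with other LPS groups gave 0 calls in limma, while the 5 others that kept the LPS groups and regrouped saline libraries gave 511, 516, 682, 696 and 1724, so the share restates the genotype difference after LPS.

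Single libraries lay far from the other 3 of their group in 10 of 116 groups of values, where chance gives about 1 in 20 groups, or 5.8. Saline replicate 4 labelled Lcn2-/- accounted for 3 of these: it had 17112 genes at 0.5 RPKM or more, a 25th percentile of -2.73 (log2 RPKM), and a mean of 5.24 for synapse genes. The other mean values of lists were 0.19 for interferon gamma genes in saline replicate 2 labelled Lcn2-/-, 2.23 and 1.72 for homeostatic microglia genes in wild type saline replicate 1 and wild type LPS replicate 3, and 2.18 for myeloid activation genes in wild type LPS replicate 4. Synapse genes lay at 5.13 in LPS replicate 1 labelled Lcn2-/-, myelin genes at 4.86 in wild type saline replicate 1, and oxidative phosphorylation genes at 6.27 in wild type LPS replicate 1.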

How the results depend on the processing

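The covariate for the block of columns in the table and the removal of GC content and length trends were chosen after seeing the data; all other alternatives were planned. No called result reversed. For named genes, 18854 of the recomputed values kept their side of the threshold, 806 were weaker and 185 stronger. For lists, 6276 kept their side, 154 were weaker and 142 stronger. The direction of values that passed in neither fit was not compared. Without the filter on low values, 13790 genes changed with LPS in wild type and 17808 in libraries labelled Lcn2-/-, 3 genes and 7 lists differed between genotypes after saline, and 905 genes had an interaction. In that setting the median LPS effect of all genes was -0.22 in wild type and -0.32 in libraries labelled Lcn2-/-, against -0.025 and -0.028 with the filter. It also moved the slope between the LPS effects to 1.005. The genes that the filter removes have low values, and the low end lay lower in LPS libraries of both genotypes. The 25th percentile over all genes was -5.78 to -4.58 there, against -4.12 to -2.73 in saline libraries. How far that shift moved the slope was not tested. At an adjusted p under 0.01, 2867 genes changed with LPS in wild type, and 3, 1023 and 265 genes passed for genotype after saline, genotype after LPS and the interaction; at 2-fold or more, 623 and 1042 genes changed with LPS in wild type and in libraries labelled Lcn2-/-, and 2, 193 and 190 passed in the other comparisons, since fewer genes meet these thresholds. Array weights gave 34 genes and 9 lists after saline, 5295 genes after LPS and 3030 for the interaction. Fits to the compared groups alone gave 3 genes after saline and 4393 after LPS. Without saline replicate 4 labelled Lcn2-/-, which enters every main test through the shared spread, these counts were 13, 5169 and 2270. How far the other settings act through that library was not tested. After saline, a filter at a mean log2 RPKM of 1 left 5 genes, and leaving out genes within 10 Mb of Lcn2 left 1. With an estimated correlation, 0 lists passed after saline, 10 after LPS and 1 for the interaction, and fry called 0 lists after saline.

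The Lcn2 difference after LPS passed limma's threshold at -0.94 with a filter at log2 RPKM 0 (adjusted p = 0.048) or a mean of 1 (0.047). At that value it also passed with quantile normalization (0.022) and the compared groups alone (6.5e-05). It passed at -0.93 and -0.92 with pseudocounts of 0.5 (9.9e-06) and 1 RPKM (6.9e-07), and at -0.96 with array weights (0.028). With the column block it passed at -0.99 (0.047), and without GC and length trends at -0.97 (0.043). It did not pass without the filter (0.068), with median centring (0.0502), without trend (0.067) or with robust moderation (0.0508). Lcn2 had an SD of 0.77 and 0.59 in the saline groups and 0.14 and 0.098 in the LPS groups. The main fit shares the spread of all groups, and the fit to the compared groups leaves the saline spread out. Causes of the other shifts were not tested.

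Leaving out each library in turn gave 3610 to 6018 genes for LPS in wild type (19 to 20 lists), 7307 to 8452 in libraries labelled Lcn2-/- (20 to 21 lists), 3 to 13 for genotype after saline (3 to 9 lists), 1511 to 5169 after LPS (14 to 17 lists) and 740 to 2270 for the interaction (15 to 17 lists). After saline the count was 3 without wild type saline replicate 2 or 3 or labelled Lcn2-/- saline replicate 1 or 3, 4 without wild type saline replicate 1 or labelled Lcn2-/- LPS replicate 2, 5 without wild type saline or LPS replicate 4, and 13, with 9 lists, without labelled Lcn2-/- saline replicate 4. After LPS it was 5169 without labelled Lcn2-/- saline replicate 4, 1511 and 1782 without labelled Lcn2-/- LPS replicates 3 and 2, and 1733 and 1750 without wild type LPS replicates 3 and 1. The interaction count was 740, 1000 and 1010 without wild type LPS replicates 1, 2 and 3, 764 and 898 without wild type saline replicates 3 and 4, 857 and 780 without labelled Lcn2-/- LPS replicates 2 and 3, and 2270 without labelled Lcn2-/- saline replicate 4. The Lcn2 difference was -0.98 to -0.88 (adjusted p 0.023 to 0.11) and passed without wild type saline replicate 1, 2 or 3 (0.036, 0.049, 0.023) or labelled Lcn2-/- saline replicate 1, 3 or 4 (0.036, 0.039, 0.032). The slope was 1.34 to 1.44, the score difference 0.58 to 0.68 after LPS and 0.53 to 0.63 for the interaction (exact permutation p 0.024 to 0.042, for any genotype effect). No paired analysis was possible because titles give running numbers, not replicate numbers. Sex was not run as a covariate because all libraries expressed Y-linked genes and little Xist, and count-based tools were not run because the table holds no counts. Without counts, the depth behind low values is unknown.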

Other observations

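The scale factor test was planned before its result was seen.

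Markers of other brain cell types also moved with LPS. In wild type brains, 7 of 14 astrocyte markers rose (8 adjusted over the list alone; camera adjusted p = 6.0e-04, and 0.039 with an estimated correlation), with Gjb6 at 0.72 ± 0.062 and Aldh1l1 at 0.50 ± 0.083 (log2, ± SE, n = 4 against 4). Oligodendrocyte precursor markers fell in 5 of 9 cases (5 adjusted over the list alone), among them the transcription factor gene Sox10 (-1.04 ± 0.066), while Pdgfra rose (0.33 ± 0.055); the list was not called (adjusted p = 0.063). Pericyte and smooth muscle markers fell in 7 of 10 cases and rose in 1 (7 and 2 adjusted over the list alone), with falls including Anpep (-1.21 ± 0.15) and the smooth muscle myosin gene Myh11 (-0.65 ± 0.10). Their adjusted p was 0.13 with an estimated correlation. Choroid plexus markers fell in 5 of 12 cases (6 adjusted over the list alone), with the potassium channel subunit gene Kcne2 at -1.65 ± 0.22 and Ttr not passing (-0.15 ± 0.068), and adjusted p = 0.42 with an estimated correlation. Of 11 leptomeningeal and fibroblast markers, 6 fell, such as Slc47a1 (-2.29 ± 0.28), and 2 rose, such as Dcn (0.68 ± 0.10), the same adjusted over the list alone, and the list was not called (adjusted p = 0.096). Neutrophil markers rose in 4 of 7 cases (the same adjusted over the list alone), with S100a8 at 2.03 ± 0.46, while Csf3r fell (-0.57 ± 0.14); the list was not called (adjusted p = 0.052). Erythrocyte markers fell in 2 of 6 cases (4 adjusted over the list alone; median -0.76, camera adjusted p = 0.039, and 0.20 with an estimated correlation). On log2(RPKM + 0.5) the changes were -0.70 for Anpep, -1.27 for Slc47a1 and -0.35 for Csf3r.

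In libraries labelled Lcn2-/-, LPS lowered Sox10 (-1.34 ± 0.066), Gpr17 (-1.94 ± 0.17), Anpep (-2.17 ± 0.15) and Kcne2 (-2.63 ± 0.22). Striatal markers fell in 5 of 9 cases (the same adjusted over the list alone), among them the dopamine receptor genes Drd1 (-0.71 ± 0.10) and Drd2 (-0.60 ± 0.079), and the list was not called (adjusted p = 0.068). Erythrocyte markers were not called either (median 0.31, 1 of 6 lower, the same adjusted over the list alone, adjusted p = 0.72). After LPS, genotype labels differed in oligodendrocyte precursor markers Bmp4 (-0.97 ± 0.16) and Gpr17 (-0.88 ± 0.17), in Anpep (-1.10 ± 0.15), and in the cerebellar marker Pcp2, a Purkinje cell gene (0.33 ± 0.052). Endothelial cell markers were lower in 4 of 12 cases (6 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation), with Tek at -0.64 ± 0.14 and Ly6c1 at -0.78 ± 0.082, while Cdh5 was higher. Anpep lay at only 0.447 and 0.209 RPKM in the LPS groups. On log2(RPKM + 0.5) it changed by -1.02 with LPS in libraries labelled Lcn2-/-, and the genotype differences after LPS were -0.42 for Anpep, -0.62 for Bmp4 and -0.29 for Tek.

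A hypothesis for the larger LPS effects is that a single scale factor applied to all genes that respond. With the Deming slope of 1.40 as that factor, 233 genes lay above and 376 below it, and camera and fry both called 5 pathway lists, 2 above and 3 below. Camera alone called 11 lists, and 0 with an estimated correlation. Among pathway lists glucocorticoid response genes departed most, with a median of -1.03, 16 of 23 genes below the slope and adjusted p = 0.054 with an estimated correlation. Erythrocyte markers, outside the pathway lists, had a median departure of 1.39 (camera adjusted p = 0.020, and 0.30 with an estimated correlation). The side of a departure does not tell whether a list changed by more or less than the factor. Myelin genes, above the slope, fell with LPS (median -0.35 in wild type and -0.39 in libraries labelled Lcn2-/-). Ribosomal protein genes, also above, had 0 of 25 members called in wild type. Glucocorticoid genes rose by a median of 1.49 in wild type and 0.88 in libraries labelled Lcn2-/-. These values argue against a factor of 1.40 for that list only. Part of its departure lies in saline, where it was higher in libraries labelled Lcn2-/- (median 0.22). The SE of the slope was not carried into the test.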
